A study of Homo sapiens with 7 samples.

How the data were processed

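The study profiled scalp skin biopsies of 2 patients with alopecia areata before oral ruxolitinib (week 0) and at week 12 of treatment, and of 3 people without the disease. Per the labels' protocols, biopsies were fixed with a PAXgene kit, RNA was extracted with a PAXgene tissue miRNA kit, amplified with the NuGen Ovation system and labelled with biotin. The authors deposited 1 table of log2 expression values for 54675 Affymetrix probe sets and 7 arrays. RMA is named in the submitters' processing notes, and its version is not given in the sources used here. RMA subtracts background, makes the arrays' distributions alike by quantile normalisation and summarises the probes of a set. That the scale is log2 was inferred from the values, which run from 1.75 to 14.3, and from RMA's usual output. Quantile normalisation assumes that most genes do not change and compresses differences in total RNA. The median of the arrays lay between 6.00 and 6.04. Arrays have no depth in reads, and their number per group limits the precision. No 2 arrays shared more than 5.95% of identical values, so all 7 were kept as separate samples.

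Probe sets were named through a table of the platform's annotation, with symbols updated by Entrez ID (41043 probe sets matched). Of the probe sets 41097 had 1 gene symbol, 1801 had several and 11777 were not listed there and stay unnamed here. Probe sets of several genes, 62 control probe sets and 59 probe sets of genes that track sex were left out. For each gene the probe set with the highest mean over all arrays was used, which gave 19740 genes. Genes were kept when at least 2 arrays reached the 40th percentile of all values (5.24), which left 15091. The bounds given for levels under that value raise each such level to it, a step added after seeing the data. Some fixed list genes had no probe set of their own and were not analysed here: 414 of the 455 list genes had one, and 385 passed the filter. No genomic coordinates were used.

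Groups came from the sample labels. All 7 arrays entered 1 linear model in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, two-sided, 3 comparisons), so that the groups shared an estimate of the spread with 4 residual degrees of freedom and 2.44 prior ones. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The 28 gene lists (13 programmes, 14 cell types and 1 of tissue handling) were written before the data were examined and share no gene. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera asks whether a list moved more than the other genes, and a preset correlation gives much smaller p-values than one estimated from 7 arrays, so the estimated version stands beside it. Fry, which asks whether a list's genes moved on balance one way, was an alternative. SE is the moderated standard error of a log2 difference, and SD is the spread between the arrays of a group.

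The week 0 and week 12 arrays pair by patient, as the labels say. The deviations of a patient's arrays from their group means correlated at r = 0.592 across genes. With 2 arrays per group the 2 pairs mirror each other and give the same r. Both arrays of patient 1 had the wider GAPDH gaps, which may enter it. The main model had no patient term, as fixed before the data were examined, and models with the patient number as a fixed block and with the subject as a random block were alternatives. The other alternatives were median centring, cyclic loess, no filter, a 60th percentile filter, the mean or the most variable probe set of a gene, every probe set, an intensity trend with a robust prior, array weights, the 2 compared groups alone, an adjusted p under 0.10, an unadjusted p under 0.05 with a 1.5-fold change, and leaving out each array. A model with the GAPDH 3' to 5' gap as a covariate and one without both arrays of patient 1 were added after seeing the data.

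The genes named were chosen by a rule fixed before the data were examined. It takes, per comparison, up to 6 called genes with the largest rise and up to 6 with the largest fall whose patients all moved that way or lay outside the control range, then up to 3 members of each list with the largest change, and a fixed panel of immune and hair genes. Within the allowance of 3, the text names 2 members of a called list and 1 of any other list, where they moved by 0.5 or more on the log2 scale, a number set after seeing the data. Classical HLA genes, immunoglobulin and T cell receptor segments and uncharacterised genes are not named.

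The model was tested on simulated data with the real means and spreads of 15091 genes, 20 runs per comparison and 200 changed genes per run. For week 12 versus week 0, 31.4% of genes changed by 1 log2 unit were recovered, 88.7% at 2, 98.8% at 4 and 99.8% at 6, with 7.95 false calls per run on average. For week 0 versus control the shares were 44.1%, 93.3%, 99.3% and 99.4% with 11.0 false calls, and for week 12 versus control 44.4%, 92.4%, 99.3% and 99.8% with 9.25. The changed genes were drawn at random from all genes, whose median residual SD was 0.22, and a patient's arrays were simulated as independent. For the hair keratin-associated protein list that SD was 1.41, so these shares do not hold for such variable genes. The shares also rest on the 200 planted changes, since the adjusted p of a gene depends on the other genes tested. For week 12 versus week 0 the real arrays gave 0 calls, so the shares may not carry over to them. A list shifted by 1 log2 unit was called in 100% of runs of each comparison, in data whose genes were simulated as independent. Figures were drawn with matplotlib.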

Results

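Gene expression was measured on Affymetrix arrays in 7 scalp skin biopsies. Alopecia areata is an autoimmune disease in which immune cells gather around hair follicles and hair is lost. Ruxolitinib is an oral inhibitor of the Janus kinases JAK1 and JAK2, which relay interferon and other cytokine signals. 2 patients with alopecia areata gave a biopsy of affected scalp before treatment (week 0) and another 12 weeks after treatment began. 3 people without alopecia areata gave a biopsy each as controls. Every value is a log2 expression level of 1 probe set per gene, and 15091 genes were tested. Arrays give no read depth, so their number, 2 or 3 per group, limits the precision. Within a group the biopsies are from separate people, so the standard errors hold the spread between people as well as between arrays. The same 2 patients gave the week 0 and week 12 biopsies, and the model used here treats these as independent. Levels under the expression filter (5.24 on the log2 scale) may be background, though no background was measured. Where an array of a named gene lies under it, a bound on the difference of the group means is given, with each lower level raised to 5.24. The gap between the 3' and 5' control probe sets of GAPDH, a sign of RNA quality, was 4.20 on the log2 scale for patient 1 at week 0 and 2.84 for patient 1 at week 12. It was 1.73 and 1.90 for patient 2 and between 1.37 and 1.89 in the controls.

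The first comparison asked how affected scalp before treatment differed from control scalp. Genes of cytotoxic T and natural killer cells were higher at week 0. The list's 21 measured genes had a median log2 difference of 1.52 (2.87-fold), and 20 of the 21 lay above the control mean (median 1.27 with levels raised to the filter value, camera adjusted p = 5.61e-15, but adjusted p = 0.121 with an estimated correlation). Granzyme A (GZMA), a killer-cell protease, was at 8.09 ± 0.24 (SD, n = 2) at week 0 and 5.70 ± 0.45 (SD, n = 3) in controls, a rise of 2.39 ± 0.28 (SE, limma adjusted p = 0.0387, and 0.0614 with the subject as a random block). Granzyme K (GZMK) rose by 1.93 ± 0.24 (adjusted p = 0.0402). Hair follicle genes were far lower. The hair keratin-associated proteins, which cross-link the hair shaft, had a median difference of -4.83 (28.4-fold lower) over 29 measured genes, all 29 below the control mean (camera adjusted p = 1.57e-21, but adjusted p = 0.22 with an estimated correlation). KRTAP8-1 was lower (adjusted p = 0.0387, and 0.0699 with the random block), with a fitted difference of -7.37 ± 0.83 (SE). Of its 2 week 0 arrays 1 lay under the filter value, so the fall of the group mean is at least 89.2-fold (-6.48 on the log2 scale). Without patient 2's week 0 array the difference was -5.94.

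**Figure D1:**
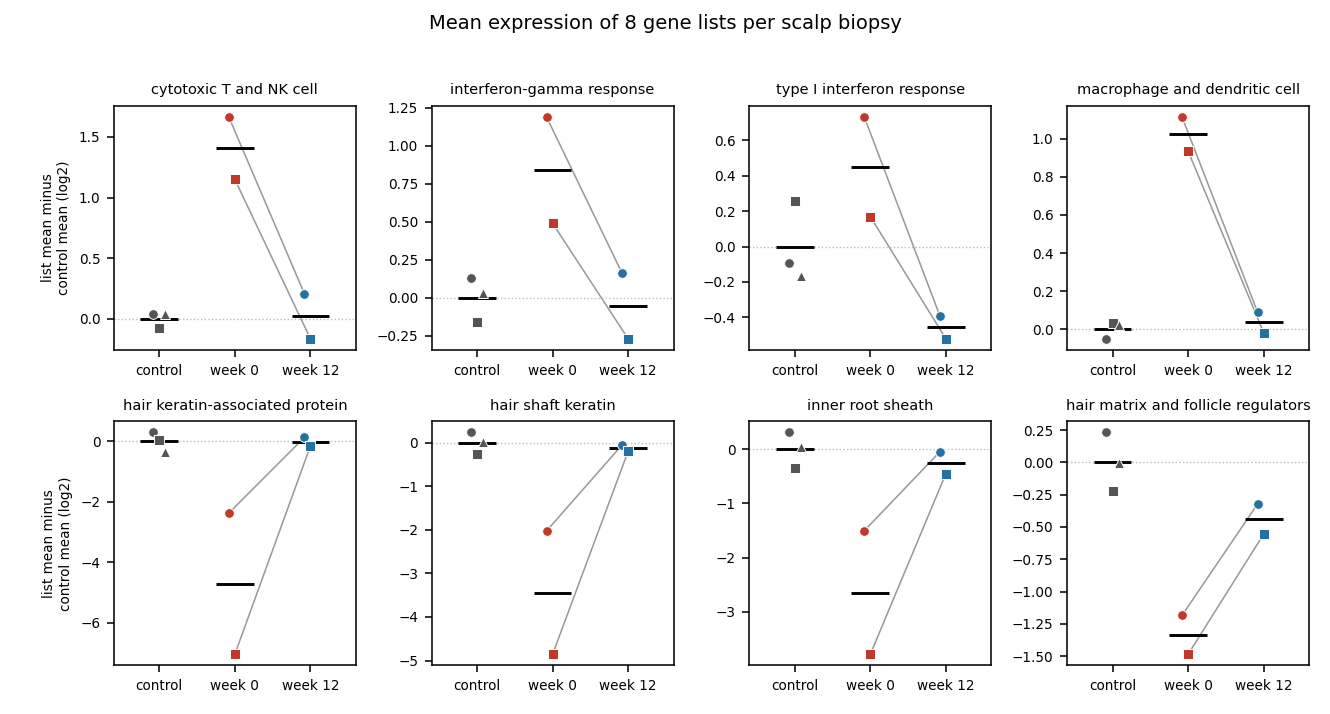
Mean log2 expression of the measured genes of 8 gene lists in each biopsy, relative to the mean of the 3 controls (vertical axis, log2 units, own scale per panel). Circles, squares and triangles are replicates 1, 2 and 3 of a group, grey lines join the arrays of one patient, and bars are group means. The cytotoxic list averaged 1.41 above controls at week 0 and 0.02 at week 12, and the hair keratin-associated protein list -4.71 and -0.01.

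At the level of single genes, 55 passed an adjusted p of 0.05 in limma, 27 higher and 28 lower at week 0. For all 55 both patients lay outside the range of the 3 controls. The 55 were selected on these same arrays, which makes such a separation likely, so it is no separate support. By fitted difference, the rises named after GZMA are XCL1, a chemokine made by killer cells, at 2.07 ± 0.18 (SE, adjusted p = 0.0357), THEMIS, a T cell signalling protein (at least 3.13-fold), XCR1, the receptor of XCL1 on cross-presenting dendritic cells, at 1.97 ± 0.18, GZMK, and GTSF1 (at least 1.25-fold, adjusted p = 0.0402). All 3 controls lay under the filter value for THEMIS and GTSF1, 2 of 3 for XCR1 (at least 3.54-fold) and 1 of 3 for XCL1 and GZMK (at least 4-fold and 3.73-fold). By fitted difference, the falls named after KRTAP8-1 are KRTAP5-8 at -5.33 ± 0.46 (adjusted p = 0.0357), the secreted cystatin CST1 (at least 5.68-fold), the hair cuticle keratin KRT32 at -3.76 ± 0.48, ZAR1 (at least 3.66-fold) and LYG2 at -3.49 ± 0.23 (adjusted p = 0.021). Both week 0 arrays lay under the filter value for CST1 and ZAR1, so the order among these genes is not measured. XCL1 was at 1.21 and XCR1 at 0.972 with the mean of their probe sets. This count is fragile. It was 0 without patient 2's week 0 array, 0 without either week 12 array, and 0, 7 and 1 without control 1, 2 and 3. Without patient 1's week 0 array it was 60, of which 13 were among the 55. It was 157 with the patient number as a block (104 higher and 53 lower, all 55 among them), 32 with the subject as a random block, 1 with array weights, 31 with the most variable probe set of a gene, 3 over every probe set and 0 when the week 12 arrays were left out of the fit. With the GAPDH gap as a covariate it was 56, 14 of them among the 55. Of the 18 genes with a call that are named for this comparison, 8 lost it with the random block. These were GZMA, KRTAP8-1, GTSF1, CST1, KRT32, CD163, HOXC13 and JAK3 (adjusted p = 0.0614, 0.0699, 0.0515, 0.0722, 0.0706, 0.0677, 0.0802 and 0.0574). The call was lost by 7 of the 18 with no filter (GZMA, GZMK, GTSF1, CST1, KRT32, CD163 and HOXC13), by 6 with the most variable probe set (GZMK, GTSF1, CTSS, CD163, HOXC13 and JAK3), by 2 with the mean of probe sets (IL12RB1 and MSX2), by 2 with an intensity trend and robust prior (GTSF1 and JAK3), by 12 with the covariate and by all 18 with array weights, with the 2 groups alone or without both arrays of patient 1.

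Of the immune lists fixed before the data were examined, 9 moved up at week 0 and the mast cell list did not (median 0.13, camera adjusted p = 0.594). Of the 21 cytotoxic genes, 3 passed over all genes tested and 18 when adjusted over the list alone. CD8A, the co-receptor of killer T cells, differed by 2.47 ± 0.33 (SE, adjusted p = 0.0514, 0.0427 with the patient block and 0.0596 with the random block), PRF1 (perforin) by 1.94 ± 0.35 (adjusted p = 0.113, 0.0387 with the patient block and 0.0895 with the random block), GZMB by 1.73 ± 0.50 (adjusted p = 0.222) and the costimulator ICOS by 0.85 ± 0.23 (adjusted p = 0.206). PRF1 was at 1.1 with the mean of its probe sets, and GZMB at 0.79 without patient 1's week 0 array and 2.68 without patient 2's. For CD8A 1 of 3 controls lay under the filter value (at least 5.49-fold), as for CXCL10, CCL18 and JCHAIN below (at least 4.24-fold, 8.24-fold and 4.59-fold). The interferon-gamma response list had a median of 0.77 over 20 genes (camera adjusted p = 9.26e-05, adjusted p = 0.22 with an estimated correlation). That median was 0.481 without patient 1's week 0 array and 1.2 without patient 2's, and the list mean lay 1.19 above controls in patient 1 and 0.49 in patient 2. The median was 0.426 with the mean of probe sets and 0.38 with the GAPDH gap as a covariate. None of its genes passed over all genes, and 6 higher and 1 lower passed when adjusted over the list alone. In this list the T cell attractant CXCL9 differed by 3.29 ± 0.61 (adjusted p = 0.114, 0.0332 with the patient block and 0.0802 with the random block) and CXCL10 by 2.37 ± 0.92 (adjusted p = 0.315). CXCL11 reached the expression filter on 1 array and was not tested. The type I interferon list had a median of 0.45 over 24 genes (camera adjusted p = 0.00174, adjusted p = 0.534 with an estimated correlation), and 0 genes passed either way. Its call was lost without patient 1's week 0 array (median 0.11, adjusted p = 0.155), without both arrays of patient 1 (adjusted p = 0.264) and with the GAPDH gap as a covariate (median 0.26, adjusted p = 0.05), and the median was 0.693 without patient 2's week 0 array. SAMD9L differed by 1.30 ± 0.49, OAS1 by 1.10 ± 0.27 and MX1 by 0.42 ± 0.35 (adjusted p = 0.309, 0.176 and 0.564). CXCL10 was at 1.45, SAMD9L at 0.588, OAS1 at 0.7 and MX1 at -0.00986 without patient 1's week 0 array. SAMD9L and MX1 were at 2.01 and 0.852 without patient 2's, MX1 at 0.671 without control 2, and SAMD9L at 0.837 with the mean of its probe sets. With the GAPDH gap as a covariate CXCL10 was at 1.05, SAMD9L at 0.466, OAS1 at 0.686, MX1 at 0.196 and GZMB at 0.878.

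Antigen presentation genes had a median of 0.47 over 12 genes, with 1 past the test over all genes and 3 when adjusted over the list alone (camera adjusted p = 0.00016, adjusted p = 0.121 with an estimated correlation), and a median of 0.887 with the most variable probe set. The lysosomal protease CTSS rose by 1.35 ± 0.14 (SE, adjusted p = 0.0386). HLA-DMB, which loads peptides onto class II molecules, differed by 1.23 ± 0.29 (adjusted p = 0.168, 0.0405 with the patient block and 0.14 with the random block). The gamma-chain cytokine and JAK-STAT list had a median of 0.50 over 23 genes, with 2 past the test over all genes and 7 when adjusted over the list alone (camera adjusted p = 6.12e-07, adjusted p = 0.121 with an estimated correlation), and a median of 0.261 without patient 1's week 0 array, 0.818 without patient 2's and 0.179 with the mean of probe sets. The receptor subunit IL12RB1 rose by 1.68 ± 0.17 (adjusted p = 0.0382, but 0.697 with adjusted p = 0.0847 for the mean of its probe sets) and the kinase JAK3, which pairs with the gamma chain, by 1.05 ± 0.13 (adjusted p = 0.0402). IL21R differed by 2.12 ± 0.36 (adjusted p = 0.104, 0.0398 with the patient block and 0.107 with the random block), the cytokine IL15 by 1.08 ± 0.35 (adjusted p = 0.256), JAK2 by 0.64 ± 0.18 (adjusted p = 0.218) and JAK1 by 0.26 ± 0.13 (adjusted p = 0.391). JAK1 turned to -0.13 with the mean of its probe sets and -0.54 with the most variable one, and JAK2 was at 0.179 with the mean. The type 2 and type 17 cytokine list had a median of 0.34 over 11 genes, 0 past the test over all genes and 2 when adjusted over the list alone (camera adjusted p = 0.00778, adjusted p = 0.194 with an estimated correlation), and its call was lost without patient 2's week 0 array (adjusted p = 0.29), while the median was 0.877 without patient 1's. It was 0.172 with no filter, 0.557 with the mean of probe sets or the most variable one, and 0.956 with the covariate. The chemokine CCL18, made by macrophages and dendritic cells, differed by 3.30 ± 0.71 (adjusted p = 0.149) and CCL20 by 1.22 ± 0.51 (adjusted p = 0.34), with CCL20 at 0.78 without control 3. IL15 was at 0.539 and JAK2 at 0.377 without patient 1's week 0 array, and with the covariate IL15 was at 0.482 and HLA-DMB at 0.781.

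Macrophage and dendritic cell markers had a median of 1.15, and all 16 lay above the control mean. 3 passed over all genes and 12 when adjusted over the list alone (camera adjusted p = 8.14e-11, adjusted p = 0.0576 with an estimated correlation). The scavenger receptor CD163 rose by 1.72 ± 0.21 (SE, adjusted p = 0.0402), and CD1C, a dendritic cell marker, differed by 1.72 ± 0.32 (adjusted p = 0.114). The 7 B cell and plasma cell markers had a median of 1.66, with 0 past the test either way (camera adjusted p = 0.000995, adjusted p = 0.22 with an estimated correlation), and the median was 0.5 without patient 1's week 0 array. It was 0.875 with no filter, 0.725 with the mean of probe sets, 0.426 with the covariate and 0.993 with levels raised to the filter value. MS4A1, which encodes CD20, differed by 2.50 ± 0.87 (adjusted p = 0.283, 0.0405 with the patient block and 0.249 with the random block) and JCHAIN by 2.26 ± 0.92 (adjusted p = 0.332). MS4A1 was at 1.12 without patient 1's week 0 array, 3.87 without patient 2's and 0.939 with the covariate, and JCHAIN at 1.36 without control 3. The 6 Langerhans cell markers had a median of 0.80, with 0 past the test over all genes and 5 when adjusted over the list alone (camera adjusted p = 0.00157, adjusted p = 0.121 with an estimated correlation), and the median was 0.503 with the mean of probe sets. HLA-DQB2 differed by 1.20 ± 0.43 and CD1E by 0.89 ± 0.21 (adjusted p = 0.29 and 0.176), with HLA-DQB2 at 0.797 without control 2 and 0.729 with the covariate, and CD1E at 0.383 with the mean of its probe sets.

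All 4 hair lists moved down. For the keratin-associated proteins 2 genes passed over all genes and 27 when adjusted over the list alone. KRTAP9-9 was under the filter value on 1 of 2 week 0 arrays and differed by at least 33.2-fold (adjusted p = 0.178). Family members of this kind are close in sequence, so a probe set may bind several of them. The hair shaft keratins had a median of -3.71 over 11 genes, with 1 past the test over all genes and 10 when adjusted over the list alone (camera adjusted p = 8.14e-11, adjusted p = 0.153 with an estimated correlation). KRT33A differed by -5.39 ± 0.79 (adjusted p = 0.068, 0.0401 with the patient block and 0.135 with the random block), KRT33B, under the filter value on 1 of 2 week 0 arrays, by at least 25.3-fold, KRT35 by -4.00 ± 1.02, KRT31 by -3.71 ± 1.10 and KRT85 by -3.64 ± 1.11 (adjusted p from 0.195 to 0.282). These values and bounds rest on the group means. Without patient 2's week 0 array KRT33B was at -1.65, KRT35 at -2.07, KRT31 at -1.58, KRT85 at -1.49, KRTAP9-9 at -3.22, KRT27 at -2.71, PADI3 at -2.4 and DSG4 at -1.47. KRT33B was at -8.54, KRT31 at -5.85, KRT85 at -5.8 and DSG4 at -6.27 without patient 1's. The inner root sheath list, the sleeve that shapes the growing shaft, had a median of -2.91 over 11 genes, with 1 past the test over all genes and 10 when adjusted over the list alone (camera adjusted p = 2.48e-08, adjusted p = 0.22 with an estimated correlation). KRT27 differed by -4.10 ± 0.72 and the peptidylarginine deiminase PADI3 by -3.65 ± 0.67 (adjusted p = 0.113 and 0.114, 0.0421 and 0.0477 with the patient block, and 0.153 and 0.166 with the random block). The hair matrix and follicle regulators had a median of -1.29 over 20 genes, with 5 past the test over all genes and 13 when adjusted over the list alone (camera adjusted p = 1.13e-12, adjusted p = 0.121 with an estimated correlation), and a median of -0.848 with the mean of probe sets. The transcription factors MSX2 and HOXC13, which act in the hair matrix, fell by 2.76 ± 0.30 and 2.30 ± 0.30 (SE, adjusted p = 0.0387 and 0.0474), with MSX2 at -1.76 for the mean of its probe sets. The cell adhesion gene DSG4, under the filter value on 1 of 2 week 0 arrays, differed by at least 6.41-fold (adjusted p = 0.264). Cell division genes had a median of -0.31 over 22 genes, 19 of them below the control mean and 0 past the test either way (camera adjusted p = 0.00112, adjusted p = 0.558 with an estimated correlation), and CCNB1 and AURKB differed by -0.79 ± 0.31 and -0.63 ± 0.23 (adjusted p = 0.315 and 0.301), or -0.441 and -0.342 without patient 1's week 0 array and -0.424 and -0.336 with the mean of their probe sets. The medians depended on the patient. Without patient 1's week 0 array the median was -7.35 for the keratin-associated list and -4.42 for the inner root sheath. Without patient 2's it was -2.24 and -1.39, -2.07 for the shaft keratins and -0.571 for cell division, which was at -0.199 without control 1, -0.542 without control 2 and -0.472 with array weights. The covariate put the inner root sheath at -4.49. The keratin-associated list lay at -2.37 relative to controls in patient 1 and at -7.05 in patient 2, and the list's median residual SD was 1.41 against 0.22 for all genes tested.

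The second comparison asked what changed in the same patients' scalp after 12 weeks of ruxolitinib. Immune lists fell and hair lists rose. The cytotoxic list fell by a median of 1.42 (2.67-fold), with 20 of its 21 genes lower in both patients (camera adjusted p = 2.32e-32, and adjusted p = 0.0466 with an estimated correlation). Macrophage and dendritic cell markers fell by a median of 0.94, all 16 lower in both patients (camera adjusted p = 1.67e-22, and adjusted p = 0.0131 with an estimated correlation). The keratin-associated list rose by a median of 4.57 (23.7-fold), all 29 genes higher in both patients (camera adjusted p = 3.68e-41, but adjusted p = 0.0962 with an estimated correlation). KRTAP8-1 went from 4.89 ± 2.02 (SD, n = 2) at week 0 to 12.94 ± 0.15 (SD, n = 2) at week 12. The difference of these group means was at least 143-fold, since 1 of the 2 week 0 arrays lay under the filter value (fitted 8.05 ± 0.91, limma adjusted p = 0.101). In patient 1, with both arrays above the filter value, the level went from 6.321 to 12.836.

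**Figure D2:**
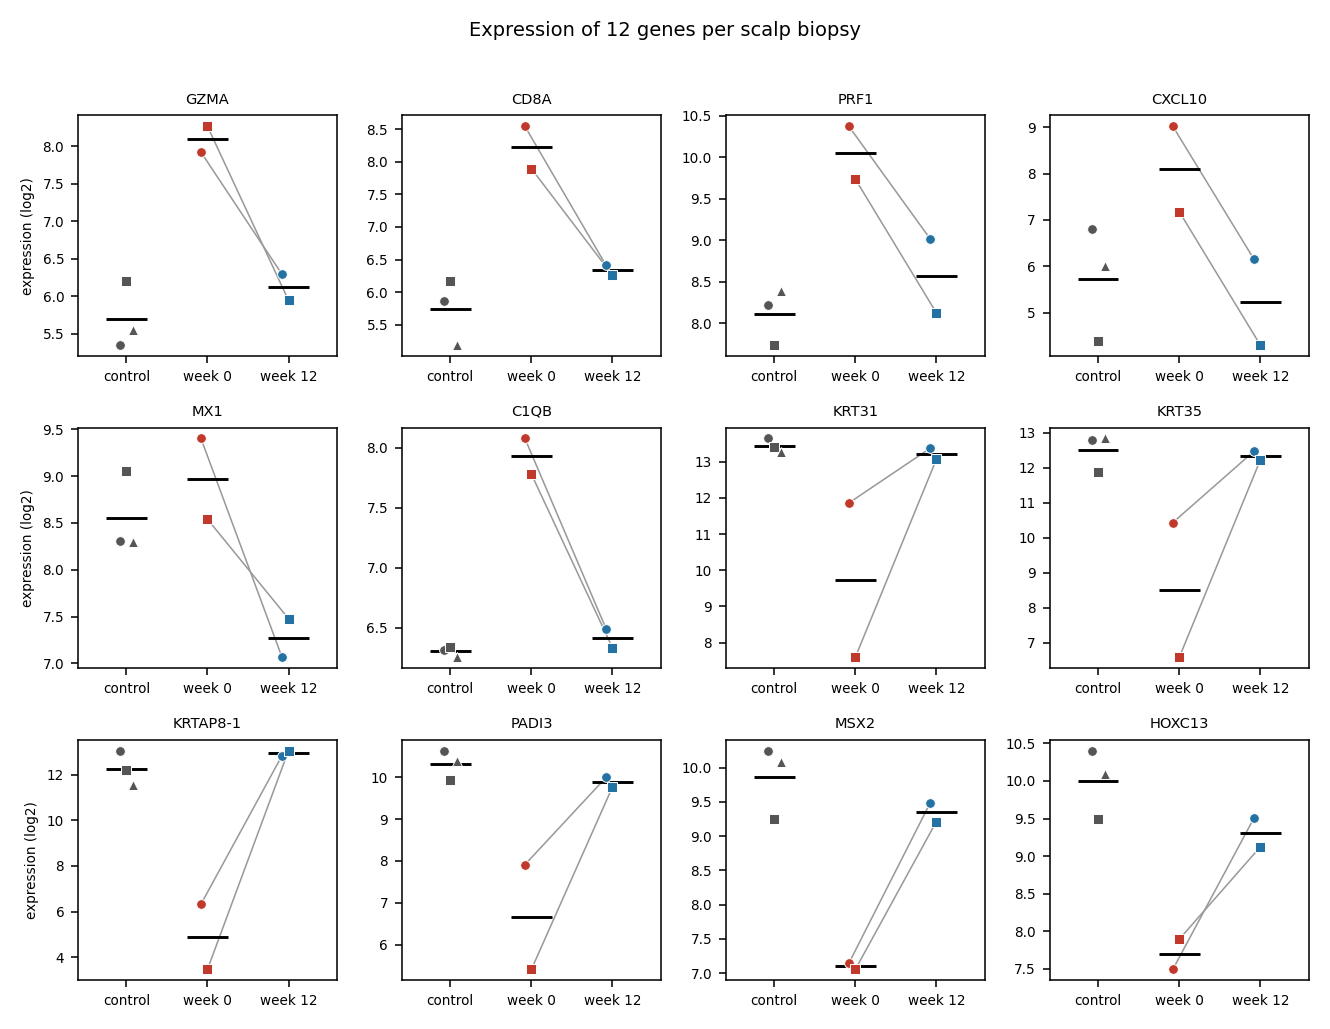
Log2 expression (vertical axis, own scale per panel) of 12 genes in each biopsy, with markers, joining lines and mean bars as in the plot of list means. CD8A averaged 5.74 in controls, 8.22 at week 0 and 6.34 at week 12, and KRT31 13.44, 9.73 and 13.22.

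No single gene passed in limma. The count was 0 of 15091, with a lowest adjusted p of 0.101. In limma 728 genes had an unadjusted p under 0.05 (251 higher and 477 lower), where 755 would by chance if all arrays were independent. The arrays of a patient were positively correlated, which lowers the number expected, so the 728 do not show an absence of change. The count of called genes was also 0 with the patient number as a fixed block. With the subject as a random block it was 223, 72 higher and 151 lower, at an estimated within-subject correlation of 0.639, which rests on the same 2 patients. Among these were, of the genes named for this comparison, IL12RB1, C1QB, GZMK, JAK3, KRTAP8-1, MSX2, CTSS, ICOS, CD8A, CCL18, CXCL9, PRF1, HOXC13, CD1E, IL21R, KRT33A, FOS, FABP4, PADI3 and HLA-DMB (adjusted p from 0.00602 to 0.0492). GZMB, CXCL10 and MX1 were at adjusted p = 0.0614, 0.0614 and 0.0559 with that block. FOS belongs to the tissue handling and stress list, which as a whole had no call. 2 settings chosen after seeing the data also gave calls, 28 genes without both arrays of patient 1 and 3 with the GAPDH gap as a covariate, all of them higher at week 12. Without patient 1's week 0 array the count was 47, again all higher.

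Among the cytotoxic genes 18 passed when adjusted over the list alone. Counts of genes higher or lower in this comparison refer to the group means unless both patients are named. GZMB differed by -2.12 ± 0.55 (SE, adjusted p = 0.551), GZMK by -2.06 ± 0.26 (adjusted p = 0.117), CD8A by -1.88 ± 0.36 (adjusted p = 0.299), PRF1 by -1.48 ± 0.38 (adjusted p = 0.551) and ICOS by -1.41 ± 0.25 (adjusted p = 0.277). PRF1 was at -0.827 with the mean of its probe sets, and GZMB at -1.18 without patient 1's week 0 array. For GZMK and ICOS 1 of 2 week 12 arrays lay under the filter value (at least 3.95-fold and 2.3-fold), as for CXCL10, CCL18 and CCR7 below (at least 5.28-fold, 11.8-fold and 2.41-fold), and both did for CCL26 (at least 1.74-fold). The interferon-gamma list fell by a median of 0.75, 19 of 20 genes lower and 0 past the test either way (camera adjusted p = 5.28e-12, adjusted p = 0.0706 with an estimated correlation), and CXCL10 and CXCL9 differed by -2.87 ± 1.01 and -2.55 ± 0.67 (adjusted p = 0.83 and 0.57). The type I interferon list fell by a median of 0.85, all 24 genes lower in both patients and 5 past the test when adjusted over the list alone (camera adjusted p = 4.85e-20, adjusted p = 0.0827 with an estimated correlation). MX1, an antiviral GTPase, differed by -1.70 ± 0.38 and IFI44L by -1.70 ± 0.68 (adjusted p = 0.394 and 0.987). Antigen presentation genes fell by a median of 0.59, all 12 lower and 2 past the test when adjusted over the list alone (camera adjusted p = 2.42e-09, and adjusted p = 0.0413 with an estimated correlation), with CTSS at -1.08 ± 0.16 and HLA-DMB at -0.96 ± 0.31 (adjusted p = 0.151 and 0.786). The gamma-chain cytokine and JAK-STAT list fell by a median of 0.56, 22 of 23 genes lower and 6 past the test when adjusted over the list alone (camera adjusted p = 6.69e-13, and adjusted p = 0.0466 with an estimated correlation). IL12RB1 differed by -1.90 ± 0.19 and JAK3 by -1.18 ± 0.14 (both adjusted p = 0.101), IL21R by -1.65 ± 0.40 (adjusted p = 0.496) and IL15 by -1.08 ± 0.39 (adjusted p = 0.854). HLA-DMB was at -0.604, IL21R at -1.09, IL15 at -0.543 and JAK2, below, at -0.301 without patient 1's week 0 array, and HLA-DMB was at -0.629 without patient 2's week 12 array. Without both arrays of patient 1 MX1 was at -1.06 and IFI44L at -0.847. With the mean of its probe sets IL12RB1 was at -0.686, and the list's median at -0.236. Of the drug's own targets, JAK2 differed by -0.56 ± 0.20 and JAK1 by -0.16 ± 0.14 (adjusted p = 0.833 and 1), and JAK1 was at 0.0047 with the mean of its probe sets. The type 2 and type 17 list had a median of -0.19, 7 of 11 genes lower and 1 past the test when adjusted over the list alone (camera adjusted p = 0.0215, 0.0671 with the patient block, and adjusted p = 0.191 with an estimated correlation). The call was also lost without patient 1's week 12 array, without patient 2's week 0 array and with no filter (adjusted p = 0.0832, 0.645 and 0.147). Its median was -0.58 and 0.0737 without the week 0 array of patient 1 and of patient 2, and -0.522 and -0.419 without the week 12 arrays. It was -0.0183 with no filter, -0.34 with the 60th percentile filter and -0.334 with the covariate. Without patient 1's week 0 array the median was -0.487 for the interferon-gamma list, -0.491 for the type I interferon list and -0.313 for the JAK-STAT list. CCL18 in this list differed by -3.59 ± 0.77 and CCL26 by -1.03 ± 0.60 (adjusted p = 0.363 and 1), with CCL26 at -0.595 without patient 2's week 0 array.

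Of the macrophage and dendritic cell markers, 13 passed when adjusted over the list alone. The complement gene C1QB differed by -1.51 ± 0.16 and CCR7 by -1.41 ± 0.53 (SE, adjusted p = 0.101 and 0.9), with CCR7 at -0.58 without patient 1's week 0 array and -2.23 without patient 2's. The Langerhans cell list fell by a median of 0.78, all 6 genes lower and 2 past the test when adjusted over the list alone (camera adjusted p = 1.12e-06, and adjusted p = 0.0466 with an estimated correlation), with CD1E at -1.12 ± 0.24 and HLA-DQB2 at -1.06 ± 0.47 (adjusted p = 0.336 and 1), and CD1E at -0.615 with the mean of its probe sets. B cell and plasma cell markers fell by a median of 0.88, all 7 lower and 0 past the test either way (camera adjusted p = 0.00249, adjusted p = 0.228 with an estimated correlation), with JCHAIN at -1.55 ± 1.00 and MS4A1 at -1.40 ± 0.95 (both adjusted p = 1). Of the 7 markers 5 were lower in both patients. MS4A1 was at -0.0201 without patient 1's week 0 array and -2.78 without patient 2's, and at -2.3 and -0.492 without the week 12 arrays. JCHAIN was at -0.865 without patient 2's week 12 array, and MS4A1 at -0.683 with the covariate. Without patient 1's week 0 array that median was -0.15 and without patient 2's week 12 array it was -0.27, and the call was lost in both (adjusted p = 0.768 and 0.135), as it was with the mean of probe sets (adjusted p = 0.0544). It was -1.33 without patient 1's week 12 array, -1.47 without patient 2's week 0 array, -0.331 with the mean of probe sets, -0.339 with no filter, -1.4 with the 60th percentile filter and -0.259 with the covariate.

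Of the 29 keratin-associated proteins 28 passed when adjusted over the list alone. The list mean rose by 2.51 in patient 1 and 6.90 in patient 2. Without the week 0 array of patient 1 or of patient 2 the median was 7.23 or 2.21 for this list, 5.41 or 1.91 for the shaft keratins and 4.37 or 1.4 for the inner root sheath. KRTAP9-9 differed by at least 28.6-fold (adjusted p = 0.616). The hair shaft keratins rose by a median of 3.49, all 11 higher and 10 past the test when adjusted over the list alone (camera adjusted p = 1.65e-19, adjusted p = 0.066 with an estimated correlation). KRT33B differed by at least 24.4-fold, KRT33A by 4.65 ± 0.86, KRT35 by 3.84 ± 1.12, KRT31 by 3.49 ± 1.20 and KRT85 by 3.44 ± 1.22 (adjusted p from 0.283 to 0.924). These values and bounds rest on the group means. Without patient 2's week 0 array KRT33B was at 1.6, KRT35 at 1.91, KRT31 at 1.36, KRT85 at 1.28, KRTAP9-9 at 3.01, PADI3 at 1.96, and KRT27 and DSG4 at 1.8 each. KRT33B was at 8.49, KRT31 at 5.62, KRT85 at 5.59 and DSG4 at 6.55 without patient 1's. The inner root sheath list rose by a median of 2.74, 10 of 11 higher and 7 past the test when adjusted over the list alone (camera adjusted p = 2.02e-14, adjusted p = 0.0962 with an estimated correlation), with PADI3 at 3.21 ± 0.74 and KRT27 at 3.14 ± 0.79 (adjusted p = 0.432 and 0.53). Hair matrix and follicle regulators rose by a median of 0.64, 17 of 20 higher and 6 past the test when adjusted over the list alone (camera adjusted p = 1.17e-12, adjusted p = 0.0706 with an estimated correlation), with DSG4 at least 7.78-fold higher, MSX2 at 2.25 ± 0.33 (1.4 with the mean of its probe sets) and HOXC13 at 1.62 ± 0.33 (adjusted p = 0.803, 0.167 and 0.333). In both patients 13 of these 20 regulators were higher. Melanocyte genes rose by a median of 0.35, 10 of 11 higher and 0 past the test either way (camera adjusted p = 3.23e-05, adjusted p = 0.191 with an estimated correlation), and the call was lost without patient 2's week 0 array (median 0.19, adjusted p = 0.122). The median was 0.653 without patient 1's week 0 array and 0.591 without patient 2's week 12 array. The pigment-cell transporter SLC45A2, under the filter value on both week 0 arrays, differed by at least 1.32-fold and the melanosome gene MLANA by 0.97 ± 0.37 (adjusted p = 0.9 and 0.909). Cell division genes rose by a median of 0.26, 18 of 22 higher and 0 past the test either way (camera adjusted p = 0.000509, adjusted p = 0.474 with an estimated correlation), with KIF20A and CENPF both at 0.55. These were at 0.246 and 0.315 without patient 1's week 0 array. KIF20A was at 0.848 without patient 2's week 0 array, and CENPF at 0.163 and 0.929 without the week 12 array of patient 1 and of patient 2 and at 0.303 with the mean of its probe sets. The list's call was lost without patient 1's week 0 or week 12 array (medians 0.118 and 0.159, adjusted p = 0.117 and 0.111) and without both (median -0.0508, adjusted p = 0.686). The median was 0.519 without patient 2's week 0 array, and the list mean changed by 0.46 in patient 1 and -0.02 in patient 2. Of the 22 cell division genes 8 were higher and 2 lower in both patients.

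In all, 19 of the 28 lists shifted between the time points in camera, 8 up and 11 down. Of these 5 held with an estimated correlation and 5 in fry, and 18 with the patient block. The 5 were the same lists in both tests, all falling (0 up and 5 down). They were the cytotoxic, antigen presentation, JAK-STAT, macrophage and dendritic cell, and Langerhans cell lists. No hair list and neither interferon list held in either test. No untreated patient at week 12 is among these samples, so treatment and time go together.

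The third comparison asked how far scalp after 12 weeks lay from control scalp. No gene passed in limma. The count was 0 of 15091 (lowest adjusted p 0.408), with 882 genes at an unadjusted p under 0.05 where 755 would by chance, and it was 0 with the patient block and with the random block. The cytotoxic list had a median difference of -0.04, the interferon-gamma list 0.01, the macrophage and dendritic cell list 0.04, the keratin-associated proteins -0.09, the hair shaft keratins -0.21 and the inner root sheath list -0.26, and none of these 6 passed in camera (adjusted p from 0.482 to 0.921). For the cytotoxic and interferon-gamma lists the patients lay on opposite sides of the controls. The cytotoxic list mean was at 0.206 in patient 1 and -0.167 in patient 2 (controls -0.075 to 0.038), and the interferon-gamma list mean at 0.160 and -0.271 (controls -0.161 to 0.129). Both patients lay within the controls' range for the keratin-associated and shaft keratin lists, and 1 of 2 for the macrophage and inner root sheath lists. CD8A differed by 0.59 ± 0.33 (SE), PRF1 by 0.46 ± 0.35, GZMB by -0.39 ± 0.50, ICOS by -0.55 ± 0.23, CXCL9 by 0.74 ± 0.61 and CXCL10 by -0.50 ± 0.92 (adjusted p from 0.81 to 0.909). With levels raised to the filter value CD8A was at 0.576, ICOS at -0.346 and CXCL10 at -0.315. Without patient 1's week 12 array PRF1 was at 0.0127, CXCL9 at -0.00865 and CXCL10 at -1.43, and without patient 2's they were at 0.908, 1.49 and 0.425. ICOS was at -0.847 and -0.257 without these arrays, CD8A at 0.317 without control 3, PRF1 at 0.273 without control 2, and CXCL10 at 0.0304 and -1.17 without control 1 and control 2. With the covariate GZMB was at -0.853, PRF1 at 0.194, CXCL9 at 0.188 and CXCL10 at -1.22. In the hair lists KRT31 differed by -0.22 ± 1.10, KRT33B by -0.05 ± 1.77, KRT35 by -0.16 ± 1.02, KRT85 by -0.21 ± 1.11, DSG4 by 0.28 ± 1.29, KRT27 by -0.96 ± 0.72, KRT38 by 1.51 ± 0.99 and KRTAP5-9 by 1.66 ± 1.05 (adjusted p from 0.81 to 0.995). KRT38 was at 0.987 without patient 2's week 12 array and 0.72 with the covariate, and KRTAP5-9 at 1.05 without patient 1's week 12 array, 2.53 without control 1 and 0.892 without control 3. The covariate put KRT31 at -1.26, KRT33B at -1.71, KRT35 at -1.15, KRT85 at -1.28, DSG4 at -0.873 and KRT27 at -1.64. These standard errors leave room for differences of more than 1 log2 unit in most of the hair keratins.

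**Figure D3:**
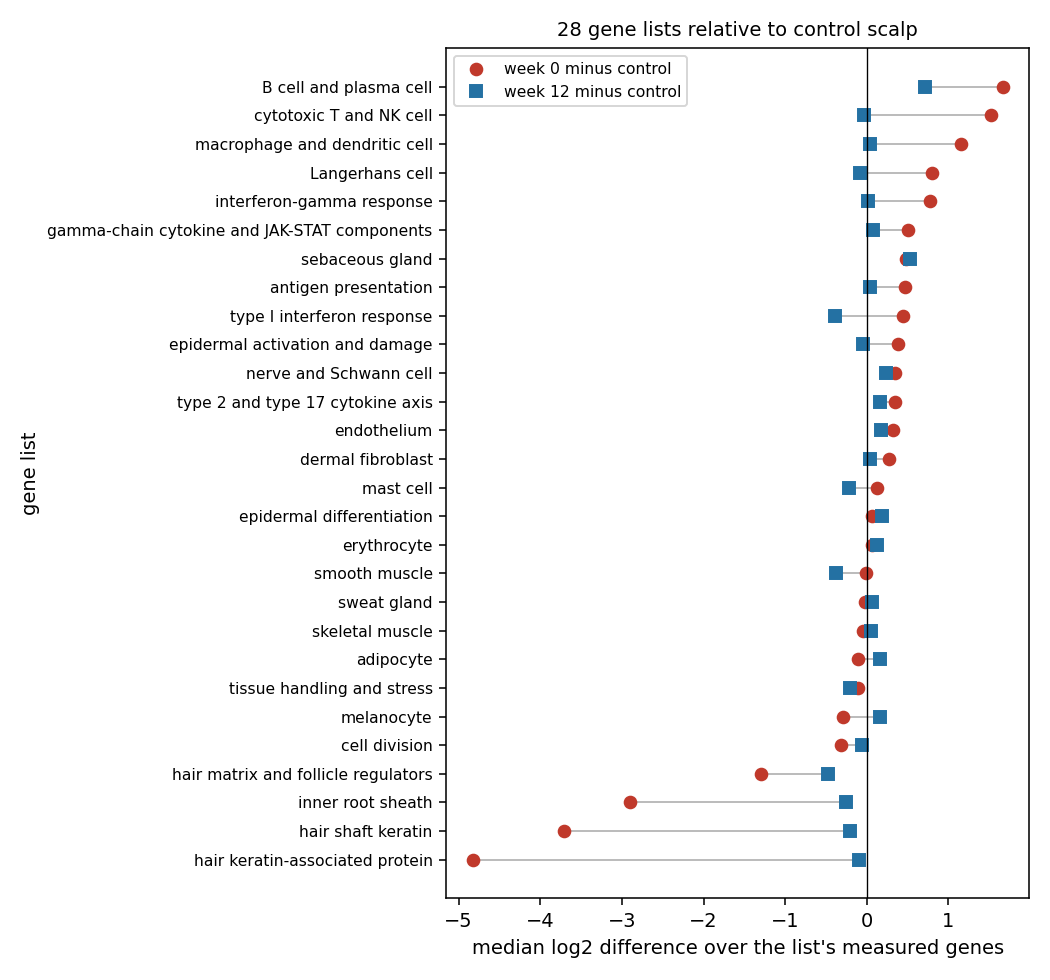
Median log2 difference from controls over the measured genes of each of 28 gene lists (horizontal axis) at week 0 (circles) and week 12 (squares), with lists ordered by their week 0 value (vertical axis). The keratin-associated proteins lie at -4.83 and -0.09, the cytotoxic list at 1.52 and -0.04, and the type I interferon list at 0.45 and -0.39.

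Lists that did differ from controls at week 12 numbered 4, with 2 up and 2 down in camera, and 0 of the 4 held with an estimated correlation. The type I interferon list was lower by a median of 0.39, with 20 of 24 genes below the control mean and 0 past the test either way (camera adjusted p = 4.25e-06, adjusted p = 0.931 with an estimated correlation), and the median was -0.244 without patient 2's week 12 array. IFI44L differed by -1.46 ± 0.62 (SE), RSAD2 by -1.33 ± 0.50 and MX1 by -1.28 ± 0.35 (all adjusted p = 0.81). Without control 2 IFI44L was at -0.915, RSAD2 at -0.803 and DSC1, below, at -1.17. The hair matrix and follicle regulators were lower by a median of 0.47, with 17 of 20 genes below the control mean and 0 past the test either way (camera adjusted p = 1.77e-05, adjusted p = 0.926 with an estimated correlation), with the desmosomal gene DSC1 at -1.78 ± 0.75, FGF5, which promotes the end of hair growth, at -0.997 ± 0.475 and HOXC13 at -0.68 ± 0.30 (all adjusted p = 0.81). The B cell and plasma cell list had a median of 0.71, with all 7 genes above the control mean (camera adjusted p = 0.0997, 0.0127 with the patient block, and adjusted p = 0.956 with an estimated correlation). It was not among the 4 lists called with the subject as a random block, and its median was 0.299 with levels raised to the filter value. Its mean was at 1.079 in patient 1, whose arrays had the wider GAPDH gaps, and 0.142 in patient 2, against 0.133 for control 2. POU2AF1 differed by 1.10 ± 0.75, and by 0.0546 without patient 1's week 12 array and 2.14 without patient 2's, and by 0.444 with the mean of its probe sets. The JAK-STAT list had a median of 0.08 and the antigen presentation list 0.03 (camera adjusted p = 0.971 and 0.994), with JAK1 at 0.10 ± 0.13, JAK2 at 0.08 ± 0.18, JAK3 at -0.13 ± 0.13 and IL15 at -0.0033 ± 0.35 (adjusted p from 0.837 to 0.999). The number of lists called was 9 with the GAPDH gap as a covariate, 12 without both arrays of patient 1, and 2 without patient 2's week 12 array. It was 8 without patient 1's week 12 array, 7 without control 2 and 7 with array weights.

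Across genes, the difference at baseline was set against the change on treatment. Because a patient's week 0 array enters both quantities, one patient's baseline was paired with the other patient's change. Pearson's r across 15091 genes was -0.372 for patient 1's baseline and patient 2's change and -0.499 for the reverse, where 100 simulations with no effect averaged -0.0016 and 0.002. The covariances were -0.124 and -0.137, against -0.00025 and 0.00029 simulated. Genes are not independent replicates, so no p-value is attached. The simulations drew every gene and array independently, whereas genes of one biopsy can move together. They therefore do not show how large r could be without an effect of treatment. Spearman's correlation averaged -0.265 over the cross-patient pairings, where Pearson's averaged -0.435. In the cross-patient pairings the list mean changed against the baseline direction for 21 and 23 of the 28 lists.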

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

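The 2 settings on RNA quality and patient 1 were chosen after the results were seen, the others before, and the cause of each shift was not tested. With 2 or 3 arrays per group, signal near background limits low genes. The fixed replicate block moved the genes at week 0 versus control from 55 to 157 and, beyond the calls printed beside it and those of POU2AF1, CD2 and KRT74 there (adjusted p = 0.0335, 0.0386 and 0.0387 with it, 0.22, 0.0672 and 0.152 with the random block), changed no other call of a list or listed gene. Other counts for that comparison were 32 with the subject as a random block, 31 with the most variable probe set, 1 with array weights, 0 with the 2 groups alone, 3 over every probe set, 109 at an adjusted p under 0.10 and 1529 at an unadjusted p under 0.05 with 1.5-fold, and 0 to 60 when 1 array was left out. For week 12 versus week 0, 0 genes became 223 with the random block, 575 at the unadjusted threshold, 28 without both arrays of patient 1, 3 with the GAPDH gap as a covariate, and 0 to 47 when 1 array was left out. For week 12 versus control 0 became 479 at the unadjusted threshold. Lists called went from 19 to 5 and 5 (week 12 versus week 0), 18 to 0 and 8 (week 0 versus control) and 4 to 0 and 0 (week 12 versus control) with an estimated correlation and in fry. The last was also 7 with array weights, 12 without both arrays of patient 1, 9 with the covariate and 2 to 8 when 1 array was left out. A group left with 1 array was assumed to vary like the others. The cross-patient correlation was -0.265 by Spearman and -0.435 by Pearson.

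No called gene reversed, and no called list's test turned, but 2 medians changed sign as their calls were lost, type 2 and type 17 (0.0737 without patient 2's week 0 array) and cell division (-0.0508 without both arrays of patient 1), both week 12 versus week 0. Genes without a call that did were JAK1 with the mean of probe sets (week 12 versus week 0 0.00468, week 0 versus control -0.132, week 12 versus control -0.127) and with the most variable probe set (-0.539 and -0.62 in the comparisons with controls), and JAK2 at week 12 versus control (-0.263 with the mean of probe sets, -0.039 with the covariate). The covariate also turned KRT19 at week 0 (0.0765) and DSG4 at week 12 (-0.873) versus control. Without both arrays of patient 1, CENPF (-0.0686) and CNN1 (0.174) turned between the time points, MX1 (-0.00986) at week 0, and CXCL9 (-0.00865) and DSG4 (-0.132) at week 12. IL15 at week 12 was 0.0016 with median centring and 0.0103 with cyclic loess. Leaving out 1 array gave week 12 versus week 0 ranges of -2.75 to 0.38 for SERPINB4, -0.366 to 1.74 for CIDEA and -1.13 to 0.0029 for CNN1, and -0.00986 to 0.852 for MX1 at week 0. At week 12 versus control the ranges were -0.00865 to 1.49 for CXCL9, -1.43 to 0.425 for CXCL10, -0.264 to 0.157 for KRT33B, -0.464 to 0.008 for KRT35, -0.132 to 0.694 for DSG4 and -0.249 to 0.243 for IL15.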

Other observations

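Sebaceous gland genes were higher in the mean of the 2 patients than in controls at both times, by a median of 0.48 at week 0 (16 of 18 genes above the control mean, camera adjusted p = 0.000995, adjusted p = 0.558 with an estimated correlation) and 0.53 at week 12 (18 of 18, camera adjusted p = 3.18e-06, adjusted p = 0.931 with an estimated correlation). Only patient 2's list means, 0.832 at week 0 and 0.983 at week 12, lay above the controls' range (-0.299 to 0.360). Patient 1's, 0.123 and 0.151, lay within it. 0 of the 18 genes passed the test over all genes or adjusted over the list alone. Both times share the same controls and patients, here and for the nerve list below, so they are not independent of each other. The steroid enzyme HSD3B1 differed by 1.25 ± 0.67 (SE) and 1.41 ± 0.67, and the neuropeptide gene GAL by 1.15 ± 0.32 and 1.06 ± 0.32. The call ended without patient 2's array of that time, at 0.30 for week 0 and 0.22 for week 12 (adjusted p = 0.384 and 0.36), and without patient 1's the medians were 0.736 and 0.827. With the GAPDH gap as a covariate the week 0 median was 0.859, and HSD3B1 was at 0.806 and 0.527 with the mean of its probe sets. Without patient 2's array of that time HSD3B1 was at 0.772 and 0.465, and at week 12 it was at 2.37 without patient 1's. Nerve and Schwann cell markers were higher by a median of 0.35 at week 0 and 0.23 at week 12, with 6 of 7 genes above the control mean each time (camera adjusted p = 0.0116 and 0.0145, adjusted p = 0.194 and 0.926 with an estimated correlation). The week 0 call was lost without patient 2's week 0 array (adjusted p = 0.0802) and with the 60th percentile filter (adjusted p = 0.105), and the median was 0.525 without control 2, 0.218 without control 3 and 0.176 with levels raised to the filter value. The week 12 call was lost with the patient block (adjusted p = 0.0705), with the 60th percentile filter (adjusted p = 0.141), without patient 2's week 12 array (adjusted p = 0.117) and without control 3 (median 0.129, adjusted p = 0.0954). That median was 0.416 without patient 1's week 12 array, and with the most variable probe set the medians were 0.692 and 0.796. Adjusted over the list alone 3 genes passed at week 0 and 2 at week 12, with the Schwann cell cadherin CDH19 at 1.25 ± 0.20 and 1.37 ± 0.20 and SCN7A at 1.02 ± 0.30 and 0.80 ± 0.30 (none past the test over all genes). With the mean of their probe sets CDH19 was at 0.409 and 0.671 and SCN7A at 0.597 and 0.431. Between week 0 and week 12 the medians of the sebaceous and nerve lists were 0.05 and -0.03, with no call, and CIDEA was at 0.69 ± 0.78 (-0.366 to 1.74 when 1 array was left out).

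Adipocyte genes rose from week 0 to week 12 by a median of 0.37, all 12 genes higher (camera adjusted p = 1.12e-06, adjusted p = 0.0824 with an estimated correlation), 2 past the test when adjusted over the list alone, and the median was 0.593 without patient 1's week 0 array. Of the 12 genes 9 were higher in both patients. The hormone gene LEP differed by 0.72 ± 0.18 (SE) and the fatty acid carrier FABP4 by 0.60 ± 0.16. At week 0 this list lay below controls by a median of 0.10 (camera adjusted p = 0.0295, 0.0576 with the patient block, and adjusted p = 0.37 with an estimated correlation), with LEP at -0.81 ± 0.16 and PCK1 at -0.77 ± 0.43. That call was lost without patient 2's week 0 array, control 2 or control 3 (adjusted p = 0.428, 0.0638 and 0.0802), with the 60th percentile filter, the mean of probe sets or the most variable probe set (adjusted p = 0.0688, 0.0815 and 0.224), and with array weights (adjusted p = 0.0951). Its median was -0.295 and -0.193 without the week 0 array of patient 1 and of patient 2, and -0.176 and -0.019 without control 1 and control 3, and it was -0.245 with the covariate. The list was at 0.16 at week 12 with no call (PCK1 -0.68 ± 0.43). PCK1 was at -1.34 and -1.12 without patient 1's array of that time and at -0.203 and -0.247 without patient 2's. Endothelial genes were higher at week 0 by a median of 0.33 (camera adjusted p = 0.0218, adjusted p = 0.518 with an estimated correlation), with TIE1 at 0.68 ± 0.25, and the call was lost without patient 2's week 0 array or control 1 (adjusted p = 0.0974 and 0.159), with the subject as a random block (adjusted p = 0.065), with the most variable probe set (adjusted p = 0.15) and without both arrays of patient 1 (adjusted p = 0.0642). The median was 0.161 without control 1 and 0.165 without patient 1's week 0 array, and TIE1 was at 0.232 with the mean of its probe sets and 0.381 without patient 1's week 0 array. From week 0 to week 12 epidermal differentiation genes rose by a median of 0.20 (camera adjusted p = 0.00169, adjusted p = 0.193 with an estimated correlation), with KRT2 at 0.70 ± 0.29. Dermal fibroblast genes fell by 0.20 (camera adjusted p = 0.00665, adjusted p = 0.386 with an estimated correlation) and mast cell genes by 0.22 (camera adjusted p = 0.0267, adjusted p = 0.386 with an estimated correlation), with the histamine enzyme HDC at -0.56 ± 0.23. In these 3 lists 0 genes passed either way. The epidermal call was lost without patient 1's week 0 array or both of patient 1's (adjusted p = 0.5 and 0.205), the fibroblast call without patient 1's week 12 or patient 2's week 0 array (adjusted p = 0.315 and 0.839), and the mast cell call without either of those or patient 1's week 0 array (adjusted p = 0.231, 0.195 and 0.0577), with the most variable probe set (adjusted p = 0.0619) and without both arrays of patient 1 (adjusted p = 0.132). Without the week 0 array of patient 1 or of patient 2 the epidermal median was 0.063 or 0.316, and it was 0.128 without patient 1's week 12 array and 0.114 with the covariate. The fibroblast and mast cell medians were -0.0527 and -0.126 without patient 1's week 12 array and -0.00669 and -0.101 without patient 2's week 0 array, and the mast cell median was -0.335 without patient 2's week 12 array. KRT2 was at 0.46 without patient 1's week 0 array, 1.09 without patient 1's week 12 array and 0.298 without patient 2's week 12 array, and HDC at -0.259 and -0.863 without the week 0 array of patient 1 and of patient 2. Mast cell genes had no call against controls. No call was made in any comparison for sweat gland, smooth muscle, skeletal muscle, erythrocyte, epidermal activation and damage, or tissue handling and stress genes. Single members with larger values were the stress keratin KRT16 at -1.89 ± 0.39 from controls at week 0 and -1.25 ± 0.39 at week 12, ALOX12B at 0.94 ± 0.49 at both times, NEB at 1.27 ± 0.42 and 1.11 ± 0.42, KRT19 at -0.95 ± 0.72 and -1.11 ± 0.72, and TAGLN at -0.71 ± 0.58 and -0.92 ± 0.58. Week 0 differed from controls by 1.38 ± 0.43 in FOS and by 0.63 ± 0.31 in HPGDS, and was lower by at least 1.73-fold in SLC4A1, whose week 0 arrays lay under the filter value. SLC45A2 was at -1.43, or -0.63 with levels raised to the filter value, which is no bound since both week 0 arrays and 1 of 3 controls lay under it. Week 12 differed from week 0 by -1.55 ± 0.47 in FOS, by at least 2.19-fold in SLC4A1, by -1.18 ± 1.05 in SERPINB4 (-0.0699 with levels raised to the filter value) and by -0.56 ± 0.52 in CNN1. Week 12 differed from controls by 0.99 ± 0.35 in SOX10, 0.82 ± 0.21 in TSLP (0.739 with levels raised), -0.84 ± 0.25 in LAP3 and -0.74 ± 0.26 in CCL19. None of these genes passed the test over all genes. When 1 array was left out, KRT19 ranged from -1.61 to -0.286 at week 0 and from -2.08 to -0.141 at week 12, and TAGLN from -1.14 to -0.185 and from -1.36 to -0.402. From controls, KRT16 was at -1.21, FOS at 0.897 and HPGDS at 0.264 without patient 1's week 0 array, and HPGDS was at 0.994 without patient 2's and 0.417 without control 1. ALOX12B was at 0.443 and 0.44 without control 2, NEB at 0.705 at week 12 without control 1 and TSLP at 0.546 without patient 2's week 12 array. With the mean of their probe sets NEB was at 0.639 and 0.625 and SOX10 at 0.593. Between week 0 and week 12, SERPINB4 ranged from -2.75 to 0.38 and CNN1 from -1.13 to 0.0029 when 1 array was left out.

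The tests in the next paragraphs were all chosen after the results were seen. Hair lists were low at week 0, and 3 technical explanations were set against that. RNA degradation would leave little once the GAPDH gap is allowed for, but the keratin-associated list mean was -6.78 ± 0.89 (SE) from controls with the gap as a covariate and -4.71 ± 1.53 without it. Only patient 1's arrays had wide gaps, so the covariate partly stands for that patient. Patient 2, whose week 0 gap of 1.73 lay within the controls' range, had this list mean at -7.05. Biopsies that missed whole pilosebaceous units would lose sebaceous genes by 1 log2 unit or more, and that list mean was at 0.478 ± 0.414. Dilution by infiltrating cells would lower the other resident genes as much, and the mean of the epidermal differentiation, dermal fibroblast, endothelium and smooth muscle lists was at 0.102 ± 0.122. These values argue against each as the whole cause. Biopsies that kept the sebaceous glands but lacked other parts of the follicle were not tested for. The adipocyte list also lay below controls at week 0 (median -0.10), a call lost in other settings. Its week 0 mean was at -0.301 in patient 2 and -0.133 in patient 1 (controls -0.164 to 0.108). From week 0 to week 12 it rose by a median of 0.37 (camera adjusted p = 1.12e-06, adjusted p = 0.0824 with an estimated correlation). The design compares patients with people without the disease, so the disease may be the reason, and what changed in the follicles was not tested.

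Immune lists fell by week 12, and 2 technical explanations were weighed. With the GAPDH gap as a covariate the cytotoxic list mean changed by -1.25 ± 0.0716 (SE), against -1.39 ± 0.23 without it, though the covariate partly stands for patient 1. In patient 2, with a gap of 1.73 at week 0 and 1.90 at week 12, the list mean changed by -1.316. Lower RNA quality at week 0, seen in patient 1 only, thus does not account for the whole change. Dilution by RNA of regrown follicles would put the resident lists at -0.693 or lower if they moved by 0.5 of the cytotoxic change, and their mean changed by -0.0897 ± 0.133. A fall in the share or activity of immune cells may remain, and whether it comes from ruxolitinib, time or the sites sampled stays open, since no untreated patient at week 12 is among these samples.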
